A study of Arabidopsis halleri and Arabidopsis lyrata subsp. petraea with 24 samples.

How the data were processed

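Per the labels, total RNA labelled with biotin was measured on Affymetrix ATH1 arrays, which carry probe sets designed on Arabidopsis thaliana. The labels name Arabidopsis halleri and Arabidopsis lyrata subsp. petraea (A. petraea below), whole root systems and rosette leaves, and plants on full mineral medium or given 25 µM zinc. The zinc concentration of the control medium is not given in the sources used here. There were 24 arrays in 8 groups of 3, and each array's group was taken from its title. The replicate number also came from the title, except that 2 arrays labelled A. halleri control roots both print number 1. The later of these in the printed serial numbers is called replicate 3 here. The labels give 23 arrays the stage of 10 to 16 rosette leaves and A. halleri control root array 1 the stage 1.1, and this array was kept. Nothing in the labels says whether the 3 arrays of a group came from separate plants, so p-values measure only the spread between these arrays, which may be technical. Where a group held arrays with leaf and with root markers (Results), that spread also holds a difference between tissues.

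The deposited values were MAS5 probe set signals, an intensity on a linear scale, per the submitters' processing notes, and the MAS5 version and settings are not given in the sources used here. MAS5 combines the perfect-match and mismatch probes of a probe set on 1 array at a time. In the deposited signals the mean without the lowest and highest 2% of probe sets was between 100.0045 and 100.0107 on every array, so arrays had been scaled to a common mean. Median signals still ranged from 43.0 to 71.5. Between 20.6% and 27.8% of an array's signals were under 16. Probes designed on A. thaliana can lose signal where either species differs in sequence, which lowers a signal without any change in transcript level and acts on comparisons between the species. Each group held 3 arrays, and that number limits the precision of every value.

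Each of the 22810 probe sets was taken as log2(signal + 16). The pseudocount of 16 damps noise at low signals and understates the change of dim genes. Probe sets whose mean over all 24 arrays lay in the lowest 25% were left out, which kept 17107 probe sets, 39 of them array control probe sets. Pairs of arrays correlated at r = 0.43 to 0.95 across these probe sets, and 0 pairs shared most of their values exactly. Gene names came from a table of the platform's annotation, which can be old: 13513 probe sets had 1 gene, 503 had several and 8794 were unnamed here. Names were given only to probe sets with 1 gene, and of several probe sets for a gene the one with the highest mean was used. This left 9560 named genes tested. No genome was used.

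limma 3.58.1 in R 4.3.3 fitted 1 model with the 8 group means to all 24 arrays, with 16 residual degrees of freedom. Variances were moderated with eBayes, with trend and robust settings, and tests were two-sided. The model had no block for the replicate number. Same-numbered control and high zinc arrays labelled A. petraea roots deviated together from their group means (r = 0.22, 0.11 and 0.38 across probe sets), a check on the values and not on a pairing the labels state, and same-numbered arrays of the sides of the other zinc comparisons did not do so at every number. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 over all probe sets tested were called. The 11 comparisons were the zinc response in each organ of each species (high zinc minus control), the species difference in each organ (A. halleri minus A. petraea, mean of both zinc levels), the difference between the species in zinc response in each organ (A. halleri response minus A. petraea response), the organ difference in each species (roots minus leaves, mean of both zinc levels) and the difference between the species in that organ difference. The script was tested on simulated data for 17107 genes with 200 changed. For the zinc response in A. halleri leaves it recovered 10% of genes changed 2-fold, 64% at 4-fold, 94% at 8-fold and 96% at 16-fold, with 5 false calls among 137. For the species difference in roots the shares were 36%, 86%, 96% and 100%, with 5 false calls among 164. The simulation drew noise for each gene independently and gave every array its right group. The real arrays share a structure that the labels do not follow. These rates therefore check the script and do not give recovery or false calls in the real data.

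Before the data were examined, 19 gene lists with 313 genes were fixed: ZIP transporters, metal efflux and vacuolar transport, metal chelation, iron deficiency, ferritins, antioxidant, heat shock, defence, glucosinolate, sulfate assimilation, phosphate starvation, cold, drought and abscisic acid, touch and wounding, circadian clock, leaf photosynthesis, root markers, suberin and lignin, cell division, and reference genes. The annotation table named only 52 of these genes and 50 were tested. The ferritin and phosphate starvation lists had 0 tested members. 1 symbol that belonged to another locus was left out. The 9 lists with 3 or more tested members were tested with camera, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment within a comparison, and again with an estimated correlation. Members of each list were also counted with limma p-values adjusted over the list alone. For a list with 1 tested member this leaves the p unchanged. It does not correct across lists or comparisons.

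The genes the text names were chosen by a rule fixed at the same time: the 8 highest and 8 lowest named genes among called probe sets whose arrays did not overlap between the sides (for differences between the species in a response, adjusted p alone); up to 4 called members of each list, or the member with the smallest p where none was called; 18 metal genes whatever their values, of which only ZIP9 and MTP8 were in the annotation table; and the 10 genes with the smallest p where fewer than 10 probe sets were called. This rule allowed 307 gene values over the 11 comparisons. After the values had been seen, this was narrowed to 162 by kind of entry and not by the value or sign of a single gene. For lists without a called member, the smallest-p member was kept only for the leaf and root marker lists and for lists whose test passed. This last condition depends on the p-values of the list tests. Genes named outside those 162 are said to be so.

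Alternatives were a pseudocount of 1 or 64, no filter or a stricter one that kept the 11405 brightest probe sets, quantile normalization, only the arrays of the groups compared, plain eBayes, limma array weights, the replicate number as a block (as printed, or with the later array of number 1 as number 3), each array left out in turn, both arrays of number 1 averaged, only probe sets bright in both species, and each zinc level alone for the species differences. Alternatives added after the data were seen left out 2 arrays on which leaf and root markers were both raised, or all arrays whose markers opposed the organ label. Other splits of the same arrays were refitted, all 10 for 3 against 3 and 100 otherwise. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.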

Results

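Transcript levels were measured on 24 ATH1 arrays from A. halleri, a zinc-tolerant species that accumulates zinc in its leaves, and from its relative A. petraea, with roots and leaves taken from control plants and from plants given 25 µM zinc. Each of the 8 groups held 3 arrays. The series title asks for the molecular bases of zinc tolerance and accumulation, so the comparisons are the response to zinc in each organ and species, the difference between the species, and the difference between those responses. Values are on the log2(signal + 16) scale, and a change is given with its standard error from limma. Ranks by size or by p-value are among genes with a name and a probe set of their own.

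Genes that mark leaf and root tissue did not follow the printed organ labels. The leaf markers were Rubisco activase (RCA), the photosystem I subunit PSAE-1, phosphoribulokinase (PRK) and sedoheptulose bisphosphatase (SBPASE). The root markers were PYK10, a beta-glucosidase of root endoplasmic reticulum bodies, and the root hair expansins EXPA7 and EXPA18. The mean of the leaf markers lay above that of the root markers on 8 of the 12 arrays labelled roots. The reverse held on 7 of the 12 arrays labelled leaves, so that 15 of 24 arrays went against their label and 9 matched it. On 13 arrays the leaf mean was higher by 3.24 to 5.83, and on 11 arrays the difference ran from -3.89 to -0.10. Leaf minus root averaged 0.55 ± 3.78 (SD, n = 12) on arrays labelled leaves and 2.50 ± 3.31 (SD, n = 12) on arrays labelled roots, a difference of -1.95 (two-sided permutation test, p = 0.183).

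**Figure D1:**
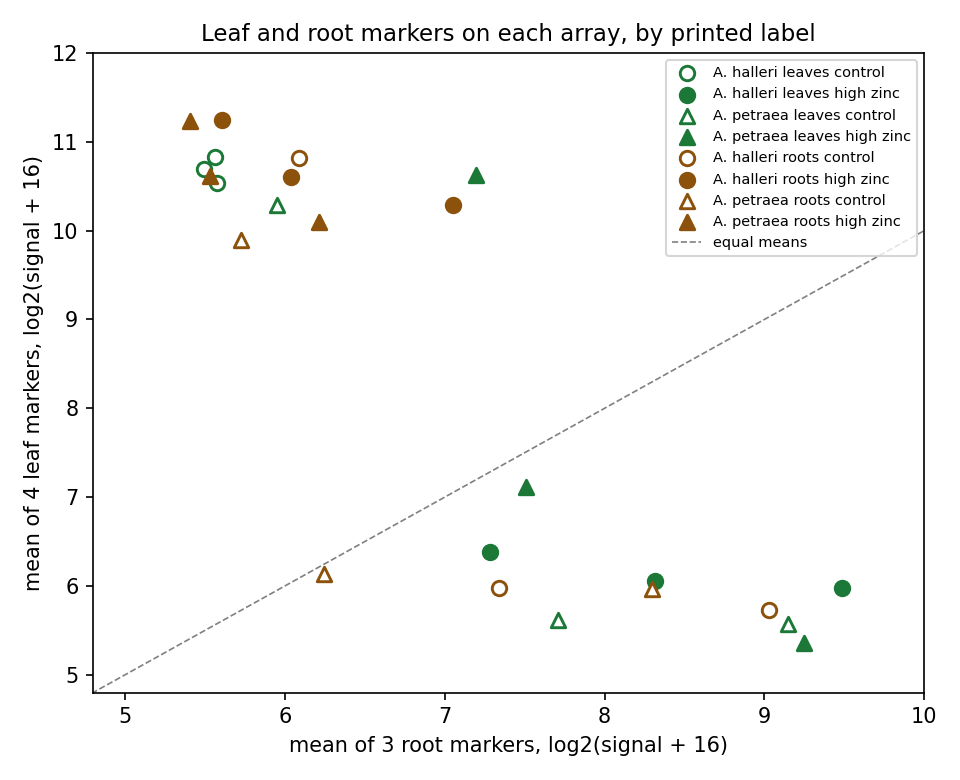
Mean of the 4 leaf markers against the mean of the 3 root markers on each of the 24 arrays, both on the log2(signal + 16) scale, with colour for the printed organ, shape for the species and filling for the zinc label. Brown points, labelled roots, lie above the line of equal means on 8 arrays, and green points, labelled leaves, lie below it on 7.

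Groups differed in how far the markers matched. Leaf minus root was 5.14 ± 0.16 (SD, n = 3) in arrays labelled A. halleri control leaves, where all 3 matched. It was -2.22 ± 1.31 in those labelled A. halleri high zinc leaves, 4.48 ± 1.203 in A. halleri high zinc roots and 4.93 ± 0.98 in A. petraea high zinc roots, 3 groups in which 0 of 3 arrays matched. The other 4 groups held arrays of both kinds, with values of 0.02 ± 4.19 in A. halleri control roots, 0.58 ± 3.30 in A. petraea control roots, -0.44 ± 4.21 in A. petraea control leaves and -0.28 ± 3.66 in A. petraea high zinc leaves. All comparisons share 1 estimate of the spread over the 8 groups. For genes that differ between leaves and roots, these 4 groups widen it. A count of 0 calls below therefore does not show that nothing differed. Only 1 of 24 arrays correlated best with an array of its own printed group. Groups below are therefore named by what the arrays were labelled, no array was moved to another group, and every direction drawn from these labels is open to the same doubt.

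**Figure D2:**
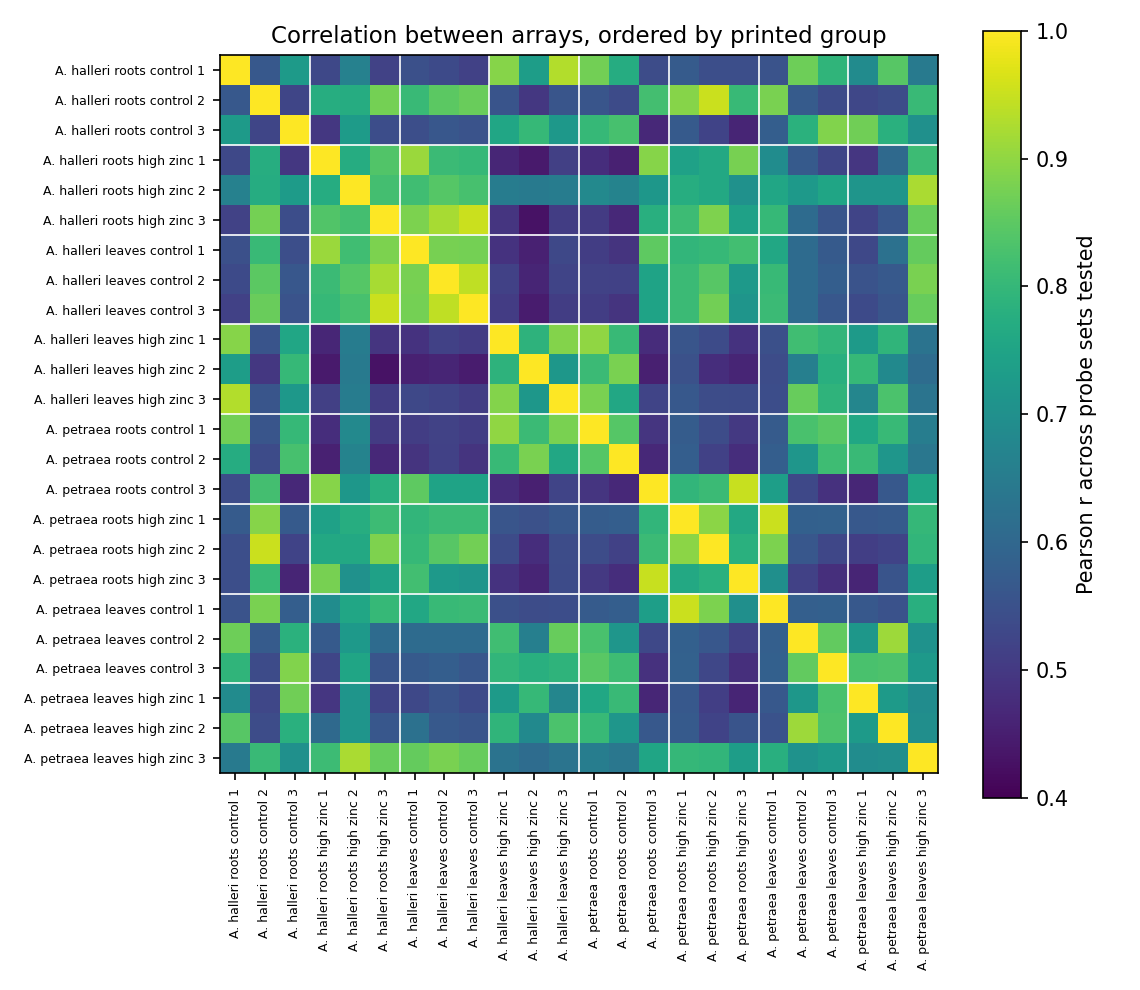
Pearson correlation across the 17107 probe sets tested for each pair of the 24 arrays, ordered by printed group, with white lines between groups. Correlations ran from 0.43 to 0.95, and blocks of high correlation crossed the printed groups.

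In arrays labelled A. halleri leaves, high zinc arrays had lower signals than control arrays for RCA, AOP3 and photosystem subunits named here, and higher signals for PYK10 and AT4G33720. Among named genes whose arrays did not overlap between the sides, large decreases included CCL at -6.90 ± 1.68, the photosystem I subunit PSAN at -6.57 ± 1.90, the antenna protein LHCB4.1 at -6.56 ± 1.84 and the photosystem II subunit PSBY at -6.32 ± 1.91. RCA fell from 12.19 ± 0.03 to 6.45 ± 0.34 (SD, n = 3 each; change -5.74 ± 1.53, adjusted p = 0.0225). AOP3, which modifies glucosinolate side chains, fell from 11.82 ± 0.34 to 4.91 ± 0.84 (change -6.91 ± 0.91, adjusted p = 0.0017). AT4G33720 rose by 7.20 ± 2.103 (adjusted p = 0.0291), AT4G25790 by 5.81 ± 1.82 and AT4G33710 by 5.17 ± 1.15. RCA, PSAN, LHCB4.1, PSBY and AT4G25790 lost their call whichever of the 6 arrays was left out, and AT4G33720 in 5 of these 6 fits.

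Other increases in this comparison were 5.81 ± 1.66 in AT1G26250, an extensin-like protein, 5.11 ± 1.58 in AT2G43610, a chitinase family member, 4.78 ± 1.47 in AT3G01190, a peroxidase, 5.06 ± 1.33 in AT4G38080 and 4.81 ± 1.55 in AT5G10580. Other large decreases were -7.56 ± 1.54 in AT1G72290, -6.68 ± 1.92 in AT1G09310 and -6.38 ± 1.42 in AT1G29670. The 8 highest and 8 lowest genes were taken by rule from called genes whose arrays did not overlap between the sides, and RCA entered as a list member. Of the 24 called genes named in this comparison, 10 had a group mean signal under the pseudocount of 16, so that the size and order of their changes depend on it. For AT4G33720, with a control signal of 7.3, the change was 8.76 with a pseudocount of 1 and 5.61 with 64, and for AT1G29670, with a high zinc signal of 3.4, it was -8.52 and -4.63.

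Among the fixed lists in this comparison, 2 of 4 leaf photosynthesis genes fell (RCA and SBPASE, the latter by 4.10 on the log2 scale) and 4 of 4 fell when adjusted over the list alone. The list test was called (adjusted p = 0.00282), but not with an estimated correlation (adjusted p = 0.282). Of 3 root markers, PYK10 rose by 4.27 ± 1.32 (adjusted p = 0.0355), and 3 rose when adjusted over the list alone, while the list test gave an adjusted p of 0.139 and 0.439 with an estimated correlation. Of 3 glucosinolate genes 1 fell, AOP3, and 2 when adjusted over the list alone, with a list test at adjusted p = 0.00425 and 0.179 with an estimated correlation. In metal efflux and vacuolar transport, MTP9 fell by 1.71 (adjusted p = 0.0285) and 7 of 8 members were not called, with 1 higher and 1 lower when adjusted over the list alone. Neither ZIP transporter tested was called, 1 rose when adjusted over the list alone, with ZIP9 at 2.40 ± 0.87 (adjusted p = 0.0589), and MTP8, a manganese transporter of the vacuole, was at 0.95 ± 0.73 (adjusted p = 0.359).

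Single members fell in the antioxidant list (thylakoid ascorbate peroxidase TAPX, -2.85 ± 0.79, 1 of 6), the defence list (the defensin PDF1.2B, -5.56 ± 1.57, 1 of 3) and the cold, drought and abscisic acid list (COR15B, -3.82 ± 1.07, 1 of 3). When adjusted over the list alone, 1 rose and 2 fell in the antioxidant list, 1 fell in the defence list and 2 fell in the cold list. The only tested member of the suberin and lignin list, FACT, rose by 2.32 ± 0.76 (adjusted p = 0.0435). In the lists for iron deficiency (4 tested), metal chelation (1), heat shock (1), sulfate assimilation (2), touch and wounding (2), circadian clock (1), cell division (1) and reference genes (5), 0 members passed limma's test over all probe sets. When adjusted over the list alone, 1 rose, that of cell division, where a list of 1 leaves the p unadjusted. The ferritin and phosphate starvation lists had 0 tested members.

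**Figure D3:**
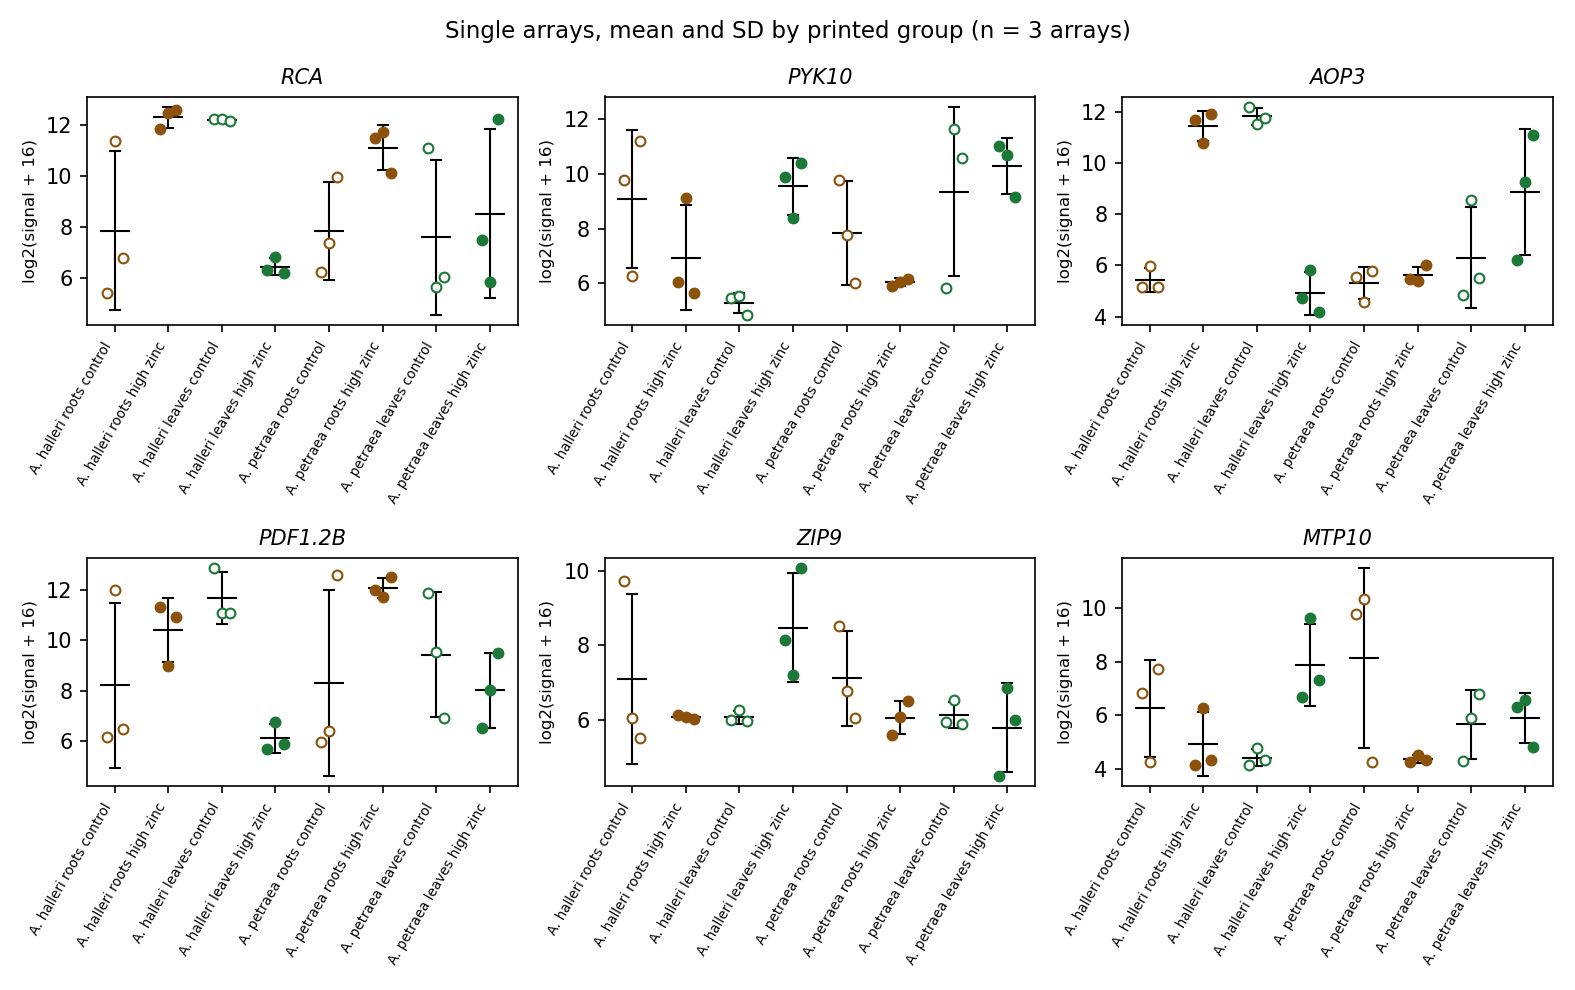
Log2(signal + 16) of 6 genes on single arrays, with 3 points per printed group and the mean and SD as a horizontal mark and bars; brown marks roots, green leaves, open points control and filled points high zinc. RCA lay between 5.45 and 12.59 over all arrays, and MTP10, named here after its values were seen, between 4.15 and 10.34.

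limma called 2949 of 17107 probe sets in this comparison, 1882 higher and 1067 lower in high zinc arrays, and 2656 of them differed at least 2-fold. Arrays of the sides did not overlap for 47.1% of probe sets tested, where chance gives 10%. The median of all probe sets was itself raised by 0.30, and quantile normalization lowered it to 0.13 and changed the split to 985 higher and 1048 lower. Organ markers moved with the comparison, since the leaf marker mean differed by -4.55. Leaf markers lay above root markers on all 3 control arrays and on 0 of the 3 high zinc arrays. The calls and gene changes of this comparison therefore cannot be told apart from a difference between leaf and root tissue. The species and zinc labels of these arrays are in doubt too (Other observations), so a difference in either may also enter. The count was 634, 1037 and 749 without control array 1, 2 and 3, and 528, 872 and 1610 without high zinc array 1, 2 and 3. Of the 24 called genes named, 4 kept their call in every one of these fits (AOP3, AT1G29670, AT1G72290 and AT4G33710) and 15 lost it in all 6, among them RCA, SBPASE, PSAN, LHCB4.1, PSBY, PYK10, PDF1.2B, COR15B and FACT.

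In arrays labelled A. halleri roots, high zinc arrays had higher signals for AOP3 and for a small set of other genes. AOP3 rose from 5.42 ± 0.48 to 11.46 ± 0.59 (SD, n = 3 each; change 6.04 ± 0.91, adjusted p = 0.0114), the opposite direction to arrays labelled leaves. In both comparisons the group with high AOP3 had leaf markers above root markers on all 3 arrays. Control leaf arrays 1 and 3 correlated best with high zinc root arrays 1 and 3 (r = 0.91 and 0.95). The opposite directions therefore cannot be told apart from organ labels that do not hold for these arrays. AOP3 did not follow the leaf markers everywhere. Arrays labelled A. petraea high zinc roots also had leaf markers above root markers on all 3 arrays, yet AOP3 was at 5.62 ± 0.33 (SD). Leaf markers alone therefore did not go with high AOP3. AT1G68600, of the aluminium-activated malate transporter family, rose by 3.71 ± 0.50 (adjusted p = 0.00601). AT2G44240 rose by 2.82 ± 0.45, AT2G15580 by 2.75 ± 0.48, AT2G44210 by 2.08 ± 0.33 and AT5G47550, a cystatin, by 1.89 ± 0.35, while AT1G77600 fell by 1.83 (SE 0.31, adjusted p = 0.0204). AT1G68600, AT2G44240, AT2G15580 and AT1G77600 had a group signal under 16, so the size of their changes depends on the pseudocount (5.73 for AT1G68600 with 1 and 2.25 with 64).

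The metal genes were not called here, with ZIP9 at -1.02 ± 0.87 (0.29 without control array 1, the opposite sign) and MTP8 at -1.11 ± 0.73. Of 3 glucosinolate genes 1 rose, AOP3, with 1 when adjusted over the list alone, and the list test was called (adjusted p = 0.00083) but not with an estimated correlation (adjusted p = 0.089). The leaf photosynthesis list was also called as higher (adjusted p = 0.00083, and 0.281 with an estimated correlation), although 0 of its 4 members were called by limma and 1 when adjusted over the list alone. RCA stood at 4.42 ± 1.53 and the root marker PYK10 at -2.15 ± 1.32, both not called. Of 6 antioxidant genes 1 rose when adjusted over the list alone. Altogether 10 probe sets were called, 8 higher and 2 lower, and the arrays of the sides did not overlap for 13.5% of probe sets tested, where chance gives 10%. The leaf marker mean differed by 3.21. Calls numbered 0, 8 and 1 without control array 1 (the array with another developmental stage in its label), 2 and 3, and 0, 15 and 1 without high zinc array 1, 2 and 3, and none of the 7 named genes kept its call in all of these fits.

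In arrays labelled A. petraea roots, no single gene passed the test. The leaf photosynthesis list was called as higher in high zinc arrays (adjusted p = 0.000169), but not with an estimated correlation (adjusted p = 0.235). None of its 4 members was called by limma, although 4 rose when adjusted over the list alone. SBPASE stood at 3.54 ± 1.32, and the leaf marker mean differed by 3.32. PYK10 stood at -1.80 ± 1.32. ZIP9 was at -1.06 ± 0.87 and MTP8 at -0.18 ± 0.73. Of 8 metal efflux and vacuolar transport genes 1 fell when adjusted over the list alone, MTP10 at -3.77 ± 1.202 (adjusted p = 0.661 over all probe sets), a gene outside the narrowed set.

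The smallest p-values in these root arrays belonged to COR27 at -1.88 ± 0.47, ATBRXL2 at -1.31 ± 0.33, AT1G04560 at -1.54 ± 0.39 and AT3G59670 at 1.14 ± 0.31, each with an adjusted p of 0.661. limma called 0 probe sets, with 1194 at an unadjusted p under 0.05. With limma array weights, which gave A. petraea control root array 3 the lowest weight of 0.234, the count was 3183. Leaving that array out gave 4. Its leaf minus root marker difference was 4.17, against -2.33 and -0.10 on control arrays 1 and 2. Leaf markers also lay above root markers on all 3 high zinc arrays. Both counts therefore cannot be told apart from a difference between leaf and root tissue.

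In arrays labelled A. petraea leaves, no gene passed the test for a response to zinc. The smallest p-values were those of AT3G42260 at 1.24 ± 0.30, CYP71B34, a cytochrome P450, at 0.98 ± 0.23, AT5G58100 at -1.48 ± 0.37, AT1G68780 at 0.93 ± 0.23 and AT2G44240 at 1.77 ± 0.45, each with an adjusted p of 1. ZIP9 stood at -0.34 ± 0.87 and MTP8 at 1.22 ± 0.73. RCA was at 0.92 ± 1.53 and PYK10 at 0.93 ± 1.32, with a leaf marker mean difference of 0.54, and the signs of RCA, PYK10 and ZIP9 turned under some alternatives. Of 3 glucosinolate genes 1 rose when adjusted over the list alone. limma called 0 probe sets, with 669 at an unadjusted p under 0.05. The call count was 1 without high zinc array 2, and 14 when all arrays whose markers opposed the organ label were left out, a fit chosen after the data were seen that left 1 array on each side.

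The difference between the species in zinc response was tested directly. In arrays labelled leaves, AOP3 differed by -9.46 ± 1.29 (adjusted p = 0.00623), with a response of -6.91 in A. halleri and 2.55 in A. petraea, where it was not called (adjusted p = 1), a value outside the narrowed set. AT1G47400, a short iron deficiency-related peptide, differed by -6.38 ± 1.35 (adjusted p = 0.0445), CYP71B26 by -4.85 ± 0.92, AT2G44240 by -4.44 ± 0.63, AT1G68600 by -4.24 ± 0.71 and AT1G73040 by -4.20 ± 0.72. AT5G53880 and AT4G22190 differed by -6.0 ± 1.28 and -4.47 ± 0.92. In the other direction stood AT3G06700, a ribosomal protein, at 4.55 ± 0.82, AT5G12280 at 3.70 ± 0.77, AT4G22120 at 2.68 ± 0.58 and AOP1 at 2.52 ± 0.50. The histone AT2G37470 followed at 2.25 ± 0.48, TET11 at 2.16 ± 0.46 and AT1G26690 at 2.06 ± 0.41. Of these 15 genes 6 had a group signal under 16 (AOP3, AOP1, AT5G53880, AT2G44240, AT1G68600 and AT1G73040), and AOP3 differed by -11.29 with a pseudocount of 1 and -7.47 with 64.

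Among the lists for this difference, glucosinolate genes (1 of 3 called, AOP3) and leaf photosynthesis genes (0 of 4 called, 4 when adjusted over the list alone) were lower, each with an adjusted p of 0.00194. With an estimated correlation these were 0.127 and 0.347. RCA stood at -6.67 ± 2.17 (adjusted p = 0.156), ZIP9 at 2.74 ± 1.22 (adjusted p = 0.264) and MTP8 at -0.27 ± 1.03, a sign that turned under some alternatives. When adjusted over the list alone, 1 gene was lower in each of the metal efflux, iron deficiency, glucosinolate and cold lists, 1 was higher and 1 lower in the antioxidant list, and 1 was higher in the suberin list. limma called 60 probe sets, 15 higher and 45 lower, while the leaf marker mean differed by -5.09 and the median of all probe sets by 0.22, or 0.11 after quantile normalization. The A. halleri response entering these calls moved with the organ markers, so they too cannot be told apart from a difference between tissues. The doubt about the species and zinc labels applies to these calls as well. Without 1 array the count was 21, 21 and 31 for A. halleri control 1 to 3, and 20, 28 and 22 for A. halleri high zinc 1 to 3. It was 73, 31 and 29 for A. petraea control 1 to 3, and 66, 70 and 20 for A. petraea high zinc 1 to 3. In all of these fits 4 of the 15 named genes kept their call (AOP3, AT1G68600, AT1G73040 and AT2G44240). AT1G68600 and AT1G73040 each lost it under 1 other alternative.

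In arrays labelled roots, the smallest p-values for a difference in zinc response were those of AT2G44240 at 3.19 ± 0.63, AT1G68600 at 3.51 ± 0.71, AOP3 at 5.73 ± 1.29 and AT4G23680 at 3.24 ± 0.74. Their adjusted p-values were 0.628 to 0.808, so they did not pass the test. ZIP9 stood at 0.03 ± 1.22 and MTP8 at -0.93 ± 1.03. SBPASE was at -1.43 ± 1.87 and EXPA7 at -0.66 ± 1.23, and the signs of both and of ZIP9 turned under some alternatives. Of 3 glucosinolate genes 1 was higher when adjusted over the list alone. limma called 0 probe sets, with 484 at an unadjusted p under 0.05, and the leaf marker mean differed by -0.11.

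Between the species in arrays labelled roots, no gene passed the test. The smallest p-values for A. halleri against A. petraea were those of AT5G27990 at -1.35 ± 0.24, CYP71B26 at 2.41 ± 0.46, AT1G68600 at 1.81 ± 0.35, AT2G18245 at -1.20 ± 0.24, AT2G39170 at -1.19 ± 0.25 and the dehydrin AT1G54410 at 3.85 ± 0.82, with adjusted p-values of 0.218 to 0.295. AOP3, in 9th place, was at 2.97 ± 0.65. MTP8 stood at -0.99 ± 0.52, EXPA18 at 1.10 ± 0.60 and RCA at 0.60 ± 1.08, and ZIP9 at -0.003 ± 0.61, with signs of RCA and ZIP9 that turned under some alternatives. When adjusted over the list alone, 1 of 3 glucosinolate genes was higher and 1 of 2 ZIP transporters lower. limma called 0 probe sets, with 942 at an unadjusted p under 0.05, while high zinc arrays alone gave 10 and leaving out A. halleri control root array 2 gave 3. The leaf marker mean differed by 0.12.

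Between the species in arrays labelled leaves, no gene passed either. AT2G20670 stood at -1.59 ± 0.32 and AT2G13870 at 1.07 ± 0.22, both with an adjusted p of 0.245 and the smallest p-values, followed by AT2G45940 at 0.87 ± 0.195 and AT3G48650 at 1.43 ± 0.32, both with an adjusted p of 0.516. The defensin PDF2.1, also among the 10 smallest, was at -2.46 ± 0.62. MTP8 was at -1.83 ± 0.52 (adjusted p = 0.812), ZIP9 at 1.31 ± 0.61 and PYK10 at -2.40 ± 0.94. SBPASE stood at 1.12 ± 0.93 and AT1G07050 at 1.34 ± 0.33, and the signs of these genes and of ZIP9 turned with 1 zinc level alone. When adjusted over the list alone, 1 gene was lower in each of the metal efflux, metal chelation and defence lists. limma called 0 probe sets, with 931 at an unadjusted p under 0.05, while control arrays alone gave 23 and leaving out A. petraea control leaf array 1 gave 3. The leaf marker mean differed by 0.98.

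Between arrays labelled with different organs, no gene passed the test in either species. In A. halleri, PSAE-1 stood at 1.11 ± 1.22 in arrays labelled roots against leaves and EXPA7 at -0.83 ± 0.62, and the leaf marker mean was higher by 0.70 in arrays labelled roots. The smallest p-values were those of AT2G20670 at 1.17 ± 0.32, AT1G31750 at -1.18 ± 0.33 and AT4G37240 at 1.54 ± 0.44, each with an adjusted p of 1. The iron deficiency list was called as lower in arrays labelled roots (adjusted p = 0.0416), but not with an estimated correlation (adjusted p = 0.344) nor under 6 other alternatives. Its member BHLH101, an iron-regulating transcription factor, was at -1.54 ± 0.49, and 0 of 4 members were called by limma, while 1 fell when adjusted over the list alone. limma called 0 probe sets, with 247 at an unadjusted p under 0.05.

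In A. petraea, the ribosomal protein AT3G06700 at 2.50 ± 0.41, AT3G60590 at 1.85 ± 0.32, the dehydrin AT1G54410 at -4.56 ± 0.82, AT5G08560 at -1.32 ± 0.24, AT5G27990 at 1.25 ± 0.24, the ribosomal protein AT5G47700 at 2.46 ± 0.47 and AT4G19200 at -3.95 ± 0.76 had the smallest p-values for roots against leaves. Each had an adjusted p of 0.0731 and did not pass the test. SBPASE stood at 1.71 ± 0.93 and PYK10 at -2.87 ± 0.94, with a leaf marker mean higher by 1.56 in arrays labelled roots. When adjusted over the list alone, 1 ZIP transporter was higher, and 1 gene was lower in each of the defence, glucosinolate, root marker and suberin lists. limma called 0 probe sets, with 2279 at an unadjusted p under 0.05. It called 374 when control leaf array 1 was left out, 1 without high zinc leaf array 1, 1 without high zinc root array 1 and 402 with array weights. Control leaf array 1 had a leaf minus root marker difference of 4.34, against -3.58 and -2.09 on control leaf arrays 2 and 3. Without it, the side labelled leaves held mostly arrays with root markers. The 374 calls therefore do not show the organ difference that the labels name.

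The organ difference itself was compared between the species, as A. halleri minus A. petraea. AT5G65685 at -3.57 ± 0.69 and AT3G06700 at -2.97 ± 0.58 had the smallest p-values (adjusted p = 0.241), followed by AT5G27990 at -1.63 ± 0.33 (adjusted p = 0.286) and AT3G60590 at -2.17 ± 0.46 (adjusted p = 0.305). PYK10 stood at 3.47 ± 1.32 and SBPASE at -1.17 ± 1.32. When adjusted over the list alone, 1 gene was higher in each of the defence, touch and wounding, and root marker lists. limma called 0 probe sets, with 1073 at an unadjusted p under 0.05, while array weights gave 118. Leaving out A. petraea control leaf array 1, the only array of its group with leaf markers above root markers, gave 20. Leaving out A. halleri control root arrays 1 and 2 in turn gave 1 and 2. The leaf marker mean differed by -0.87.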

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

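The splits of the arrays and their expected outcomes were set before their results were seen, and no test in this part was chosen afterwards. In a test of the difference between the species' zinc responses in arrays labelled leaves, limma called 60 probe sets. Those that the rule for named genes takes were AOP3 (-9.46), AT1G47400 (-6.38), AT5G53880 (-6.0), CYP71B26 (-4.85), AT4G22190 (-4.47), AT2G44240 (-4.44), AT1G68600 (-4.24) and AT1G73040 (-4.20), and in the other direction AT3G06700 (4.55), AT5G12280 (3.70), AT4G22120 (2.68), AOP1 (2.52), AT2G37470 (2.25), TET11 (2.16) and AT1G26690 (2.06), all log2 differences. Other splits of the same 12 arrays, within each species, bear on whether this count is more than grouping by luck gives. Of 100 splits, 5 reached 60 calls, the real one included, and the highest of the others called 2567, so chance is not excluded. A split that calls many times the real count points to a structure in the arrays that the labels do not follow.

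For the other comparisons, the same splits gave these outcomes. The zinc response in A. halleri leaves had a real count of 2949 and the highest other split had 0, and A. halleri roots had 10 and 0. Here 3 arrays against 3 make only 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, reached the real count in each. In the other 8 comparisons the real count was 0, which any split reaches (10 of 10 for the zinc response in A. petraea roots and leaves, 100 of 100 for the rest), so these splits test nothing about chance. The highest other split called 12 for zinc in A. petraea roots and 1 in A. petraea leaves. The highest other split called 37 for the species in roots, 73 for the species in leaves, 3088 for the species difference in zinc response in roots, 1692 for organs in A. halleri, 2232 for organs in A. petraea and 1 for the difference between these. The counts of 3088, 1692 and 2232 again point to a structure in the arrays apart from the labels.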

How the results depend on the processing

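The 2 fits that left out arrays by their organ markers were chosen after the data were seen, and the other alternatives were planned. Counts of calls kept their size within 1.5 times under the alternatives not listed here, and the cause of each move was not tested except where fewer arrays or probe sets entered by construction. Calls for the zinc response in A. halleri roots numbered 17 with a pseudocount of 64, 6 with only the brightest 11405 probe sets, 1 with only the arrays compared, 22 with array weights, 1 with both arrays of number 1 averaged and 27 without the 2 arrays with raised leaf and root markers, labelled A. halleri high zinc root 2 and A. petraea high zinc leaf 3. Array weights gave 3183 for A. petraea roots, 8797 for A. halleri leaves, 7 and 94 for the species in roots and leaves, 2881 for the species difference in leaf zinc response, 402 for organs in A. petraea and 118 for the organ difference between species. With only the arrays compared, A. halleri leaves gave 4764, the species in roots 1, and the species difference in zinc response 1 in roots and 161 in leaves. That last count was 35 with a pseudocount of 1. Without the 2 raised-marker arrays it was 15, with 3 in roots and 4 for the species in roots. Without the arrays opposing their organ label, A. petraea leaves gave 14, 3 higher and 11 lower, from 9 arrays with 4 residual degrees of freedom, and no other comparison could be computed. There the lone array on each side is assumed to vary like the other groups. High zinc arrays alone gave 10 for the species in roots, control arrays alone 23 for the species in leaves, and the averaged arrays 1 for the organ difference between species.

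With 1 array left out, counts ran from 0 to 15 for zinc in A. halleri roots, 0 to 4 in A. petraea roots, 528 to 1610 in A. halleri leaves and 0 to 1 in A. petraea leaves. They ran from 0 to 3 for the species in roots and in leaves, 0 to 0 and 20 to 73 for their difference in zinc response in roots and leaves, 0 to 0 and 0 to 374 for organs in A. halleri and A. petraea, and 0 to 20 for the difference between these. With the replicate block, A. halleri roots gave 7 with numbers as printed and 11 with the other numbering, A. halleri leaves 2647 and 2492, the species difference in leaf zinc response 41 and 45, and the other comparisons 0. Deviations of same-numbered arrays from their group means correlated above 0.1 in 26 of 84 pairs (median -0.041, range -0.53 to 0.60), and at all 3 numbers in 3 of 28 pairs of groups. Among these were control and high zinc A. petraea roots, whose count of calls stayed 0 with the block. These checks took the later A. halleri control root array of number 1 as number 3. With that numbering, 10 of 24 arrays correlated best with their own number.

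Of the 162 gene values named, other alternatives gave 1843 values: 1710 kept direction and side of the threshold, 59 lost the call, 62 gained it and 12 changed sign. Leaving out 1 array gave 1698 values: 1414 kept both, 241 lost the call, 22 gained it and 21 changed sign. Most of the 162 values were not called in Results, and one that stays uncalled counts as kept. Called ones numbered 7 for zinc in A. halleri roots, 24 in A. halleri leaves and 15 for the species difference in leaf zinc response. Of these, 0, 4 and 4 kept their call in every fit with 1 array left out, and 0, 4 and 2 under every alternative. The narrowing to the 162 values was made after values were seen. Over all 307 values the rule allowed, 45 of 3574 and 95 of 3324 changed sign, a larger share. Sign changes were ZIP9 at 0.071 in A. petraea leaves without arrays opposing their label, RCA there at -0.92 without the 2 raised-marker arrays, and PYK10 there at -0.42 with array weights. For the species in roots ZIP9 was 0.057 with a pseudocount of 64, 0.015 with the replicate block as printed and 0.014 with high zinc arrays alone. For the species in leaves ZIP9 was -0.056 with control arrays alone, and SBPASE -1.09 and AT1G07050 -0.70 with high zinc arrays alone. For the difference in zinc response, ZIP9 in roots was -0.12 with a pseudocount of 64 and -0.002 with the replicate block as printed, and MTP8 in leaves 0.16 with a pseudocount of 1.

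With 1 array left out, ranges that crossed 0 were ZIP9 from -1.81 to 0.29 in A. halleri roots, ZIP9 from -0.87 to 0.31, RCA from -0.92 to 2.66 and PYK10 from -0.83 to 2.08 in A. petraea leaves, RCA from -0.27 to 1.202 and ZIP9 from -0.66 to 0.39 for the species in roots, SBPASE from -2.68 to 0.15, EXPA7 from -1.61 to 0.41 and ZIP9 from -0.76 to 1.34 for the difference in root zinc response, and MTP8 from -1.03 to 0.27 for that in leaves. Of 64 list alternatives 50 kept their call and 14 lost it. All 8 called lists lost it with an estimated correlation, and the iron deficiency list in A. halleri organs lost it under 6 more, with adjusted p from 0.0533 to 0.377. The other 7 kept theirs under the pseudocounts, filters, quantile normalization and replicate blocks. Lists were not tested with an array left out, nor under the remaining alternatives. The brightness of the arrays sets a limit of its own, since up to 27.8% of signals lay under the pseudocount of 16. Control probe sets that bear on RNA quality also varied between arrays. The 3' minus the 5' probe set of actin ran from -0.09 to 3.71 on the log2 scale. The 25S ribosomal RNA probe set ran from 6.33 to 14.14. No comparison took these into account.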

Other observations

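The explanations for the organ markers in this part were tested only after the marker values had been seen, by tests chosen then. Single genes fell into separate sets of arrays whatever the printed groups. RCA lay at or under 7.50 on 11 arrays and at or above 9.95 on 13, SBPASE at or under 6.82 and at or above 9.50, and PSAE-1 at or under 6.86 and at or above 9.51, with the same numbers of arrays. The cold-regulated genes COR15A and COR15B also parted into 11 and 13 arrays at their widest gaps, at 6.21 to 7.12 and 6.57 to 7.70. PYK10 parted into 11 arrays at or under 6.28 and 13 at or above 7.75.

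AOP3 was at or under 6.21 on 15 arrays and between 8.55 and 12.19 on 9. F6H1, an enzyme of scopoletin synthesis induced by iron deficiency, parted into 14 arrays at or under 7.40 and 10 at or above 9.70. High values on few arrays were seen for MTP10, at or above 9.62 on 3 arrays, and ZIP9, at or above 9.72 on 2. PDF2.1 was at or above 8.16 on 3 arrays. These genes include some outside the narrowed set and were chosen after their values were seen.

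Why the organ markers oppose 15 of 24 labels is the pattern a reader would want to follow up. An effect of zinc on the markers is argued against as the sole cause, because 4 of 12 arrays labelled control also opposed their label, against 11 of 12 high zinc arrays. An exchange of organ labels between whole groups is argued against because 4 of 8 groups held arrays of both kinds. A candidate explanation is that titles were attached in the text order of the printed serial numbers, in which 10 sorts before 2: under that order 23 of 24 arrays had the markers of the organ it gives, against 9 as printed, and the highest of 10000 random relabellings reached 21. The exception was A. petraea high zinc leaf array 3, where leaf and root markers were both raised.

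A second pattern bears on the same hypothesis, with correlations over all probe sets tested, the markers among them. Only 1 of 24 arrays correlated best with an array of its printed group. Under the text order, 19 of 24 arrays correlated best with the array of the same number, organ and species at the other zinc level. As printed 4 did, a contrast that also holds the organ mismatch given above. The highest of 10000 shuffles within organs, which keep the organ fixed, gave 12. The pattern may reflect titles attached in text order, and it was found and tested on the same data. If so, the species and zinc labels would move together with the organ labels. Every comparison above would then set other samples against each other than its name says. For example, the arrays labelled A. halleri control leaves would be those of A. petraea high zinc leaves. No comparison was recomputed under another order, and the original array records were not used here.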
